A study of Mus musculus with 16 samples.

How the data were processed

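RNA from mouse submandibular glands was sequenced in 10 libraries, 5 groups of 2. The groups were unirradiated glands taken at ZT3, ZT9 and ZT15 (zeitgeber time, hours after lights on) and irradiated glands taken 6 h and 24 h after a dose of 5 Gy. CUT&Tag, in which an antibody directs a transposase to the chromatin around a bound protein, gave 6 lists of summits, 2 for each of 3 targets: Bmal1 (the product of Arntl), Nr1d1 and Dbp. The labels name the target under genotype rather than as an antibody, and they give no control sample for the CUT&Tag. They do not give the sex of the mice or the clock hour of irradiation, and nothing in them says that replicates were separate animals. The p-values therefore measure the spread between these samples.

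The expression values are FPKM per gene (fragments scaled to transcript length and mapped fragments), computed by the authors. HISAT2, SAMtools, Cufflinks and Bowtie2 and the mouse build mm10 are named in the submitters' processing notes, without the role of each tool. Their versions are not given in the sources used here, and the annotation behind the FPKM is not stated. The CUT&Tag files hold 1-bp summits with a deposited score per summit. The peak caller, its control, its threshold and the scale of the score are not stated, so scores were used only to rank summits within a list. The labels give gene symbols only, so genes are named by symbol.

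Each expression file held 55398 entries. The 217 entries whose symbol occurred more than once, 107 symbols in all, were left out, and 55181 genes were joined by symbol. The files came in 2 gene orders, 1 shared by the ZT3 and irradiated libraries and 1 by the ZT9 and ZT15 libraries. Genes with an FPKM of at least 1 in at least 2 libraries were kept, 15161 genes. FPKM values carry no counts, so the depth of each library is unknown and no counting interval was computed. A relative depth was read from the commonest ratio between libraries among genes of low abundance. The number of libraries per group limits the precision.

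The kept values were transformed as log2(FPKM + 1) and fitted with limma 3.58.1 in R 4.3.3, with a mean-dependent prior (trend) and 1 mean per group over all 10 libraries, which left 5 residual degrees of freedom. Two-sided moderated tests were adjusted by the Benjamini-Hochberg method over the kept genes, and a gene was called at an adjusted p under 0.05. Before the data were examined, ZT9 was chosen as the control for 6 h and ZT3 as the control for 24 h, along with the gene lists, the naming rule and most alternatives. The ZT3 controls are tagged as the starting point in their descriptions, which is the reason for that pairing. The control times were compared by an F test and in pairs, and the change at 24 h minus the change at 6 h was tested as a contrast of its own. With 2 libraries per group, an exact permutation test cannot reach an adjusted threshold, and no test of other groupings or of outlying libraries applies.

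The gene lists covered the core clock, PAR bZIP clock output, p53 targets, DNA repair, proliferation, acinar secretory products, fluid and ion secretion, granular convoluted tubule, duct cells, myoepithelial and basal cells, T cells, B cells, plasma cells, macrophages, neutrophils, interferon response, inflammatory cytokines, heat shock, cold-inducible genes, glucocorticoid response, immediate early genes, unfolded protein response, fibroblasts and matrix, endothelial cells, adipocytes, skeletal muscle, blood cells, parotid and pancreas-like products, sex-linked genes, mitochondrial transcripts and cholesterol synthesis. The 29 lists with at least 4 kept genes were tested with camera, which compares a list with all other genes, at a preset correlation between genes of 0.01, and again with the correlation estimated from the libraries. Adjusted p-values of lists are over those 29. Cold-inducible genes and parotid products kept too few genes for camera and are given as values. For each list, calls are counted over all genes and adjusted over the list alone.

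The genes named for a comparison were up to 8 with the largest rise and up to 8 with the largest fall among called genes with a mean FPKM of at least 5 in the higher group and no overlap between the libraries of the groups, leaving out predicted and clone-named genes. They also included core clock and PAR bZIP genes and up to 4 called members of each other list with the smallest p. Where fewer than 5 genes passed, the 5 with the smallest p were named. Any other gene is said to have been chosen after its values were seen. For the summits, the clock genes and the 5 regions per target with the highest deposited score in both lists were named.

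Summits on chromosomes 1 to 19, X and Y were compared in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1; figures were drawn with matplotlib 3.10.9. Since the summits span 1 bp, each was given 100 bp on either side, so that summits within 200 bp overlap. Chance overlap came from 100 circular shifts of the summits within chromosomes. A region found in both lists of a target joined overlapping summits of its lists. Genes were located with a RefSeq gene table of the build GRCm38.p6, which has the coordinates of mm10 but was used without strand, so a summit within 1 kb of either end of a protein-coding gene (21887 genes) was counted in place of a transcription start site. Summit sequences were not analysed here, so the planned motif test was not run. Regions were set against RNA changes with a two-sided Fisher's exact test over 14286 kept genes found in the table, and against 10000 random lists matched on mean FPKM in 20 bins.

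The fits were tested on simulated data with known changes, and the overlap count was tested on a list with 30% of summits planted, of which 30.2% were found. In the simulated data the noise was independent between genes and genes of low abundance were not changed. Noise in the real libraries is shared between genes, as in the sex-linked, amylase and lymphocyte transcripts below. The recovered shares may therefore overstate the power of the real comparisons. Alternatives tried were a pseudocount of 0.1, no filter, a mean FPKM of at least 5, median-of-ratios scaling, quantile normalization, the replicate number as a term, robust moderation, a fold-change minimum, only the groups compared, each library left out in turn, other controls, a summit distance of 100 bp, the higher-scoring part of each list, a gene-end distance of 5 kb and regions in either list. Alternatives chosen after seeing the data were a term for the presence of Y-linked transcripts (for genes, for lists and with the mean of 3 control times), terms for Amy1 and for the B cell list, leaving out ZT15 replicate 2 from comparisons without it, a wider summit distance, a sign test of the ranks of clock genes in the Bmal1 and Nr1d1 lists and an unadjusted p for changed genes.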

Results

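The study measured gene expression in the mouse submandibular gland, a salivary gland, through the day and after ionising radiation, together with chromatin binding of 3 clock proteins; its title names the circadian clock and loss of salivary function after radiotherapy. RNA-seq covered unirradiated glands at ZT3, ZT9 and ZT15 and glands 6 h and 24 h after 5 Gy, with 2 libraries in each group. CUT&Tag gave 2 lists of summits for each of Bmal1, Nr1d1 and Dbp. The total FPKM per library ranged from 791786 to 1174465, with 19195 to 21781 genes above 0. The depth in reads is unknown; relative to ZT3 replicate 1, the depth read from the FPKM steps ranged from 0.690 in ZT9 replicate 1 to 1.58 in replicate 1 at 24 h. Scgb1b27, a secretoglobin of the gland, took 8.21% to 24.6% of the FPKM of a library. Values below are mean FPKM ± SD of 2 libraries unless a single library is named.

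The libraries differed in ways their groups do not explain. Y-linked transcripts (Ddx3y, Kdm5d, Eif2s3y and Uty) had a mean FPKM of 18.7 to 30.7 in both ZT3 libraries, ZT15 replicate 2 and replicate 1 of each irradiated group, where Xist, the RNA of the inactive X chromosome, was at most 0.0688. In both ZT9 libraries, ZT15 replicate 1 and replicate 2 of each irradiated group the Y-linked transcripts were listed at 0 and Xist was 24.9 to 58.3. Amy1, an amylase abundant in the parotid gland, was 26.4 and 4167 in the ZT3 libraries, 12.8 and 1108 at ZT9, 111 and 19203 at ZT15, 6939 and 9935 at 6 h and 4585 and 343 at 24 h. The mucin Muc19 was 0.274 in ZT9 replicate 2, and the acinar product Prol1 was listed at 0 in replicate 1 at 24 h. Amy1, Muc19 and Prol1 were picked out after their values were seen.

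At 6 h after irradiation the glands had a p53 response. Of the 30 targets of p53, the transcription factor activated by DNA damage, 19 rose against ZT9, 28 when adjusted over the list alone, and all 30 were higher, with a median log2 change of 1.85 (adjusted p = 1.7e-41; adjusted p = 0.013 with an estimated correlation). Cdkn1a, which halts the cell cycle, went from 1.58 ± 0.539 to 71.3 ± 0.787, a log2 change of 4.83. Ccng1, a cyclin induced by p53, went from 27.2 ± 2.52 to 219 ± 19.9, and Phlda3, an inhibitor of Akt signalling, from 10.8 ± 0.185 to 76.1 ± 7.40. Polk, a polymerase that copies damaged DNA, went from 1.81 ± 0.165 to 17.1 ± 1.29. The largest rises also included the death receptor Eda2r (log2 change 3.75), Trp53inp1 (3.40), Gtse1 (3.24), Fgfbp1 (2.92), the nuclease Aen (2.88) and Ddias (2.77).

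**Figure D1:**
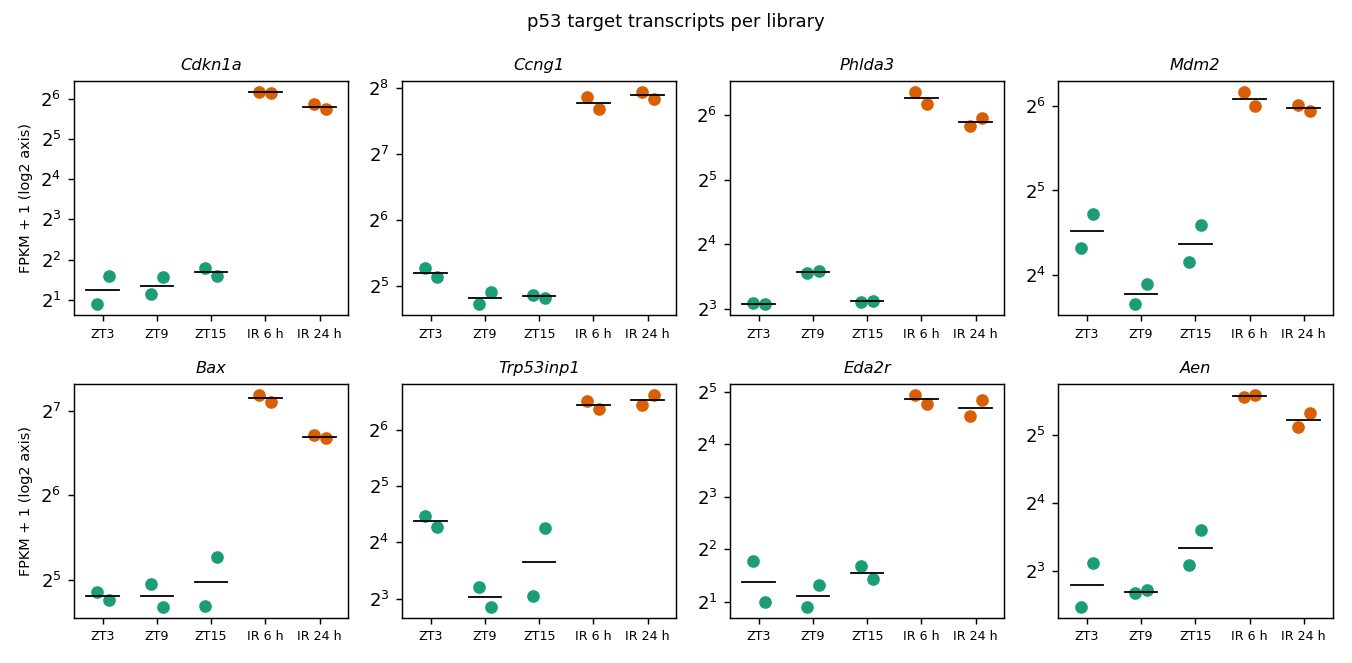
FPKM + 1 (log2 axis) of p53 target transcripts in each library, by group; points are libraries (green, unirradiated; orange, irradiated) and lines are means on the log2 scale. Cdkn1a was 71.3 at 6 h and 55.3 at 24 h, against 1.58 at ZT9 and 1.44 at ZT3.

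Of the genes that fell at 6 h, Slc7a5, which carries large neutral amino acids into cells, went from 62.0 ± 14.4 to 16.6 ± 2.25, and Slc1a4, a transporter of serine and alanine, from 9.99 ± 2.40 to 2.49 ± 0.784. Gpt2, an alanine aminotransferase, went from 64.6 ± 6.51 to 26.4 ± 4.69, and Asah2, a ceramidase, from 15.9 ± 3.43 to 5.48 ± 0.314. Against ZT3 instead of ZT9, Slc7a5 was higher by 0.23 and Gpt2 by 0.0182 on the log2 scale, neither called. Slc1a4, at 2.89 ± 0.160 at ZT3, was not called against that time either, while Asah2, at 15.9 ± 1.25, was. Sdc1, a proteoglycan of epithelium and of plasma cells, rose from 6.32 ± 0.341 to 20.8 ± 2.01, and was the only called member of the plasma cell list.

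None of the 18 core clock genes or 4 PAR bZIP genes (Dbp, Tef, Hlf and their antagonist Nfil3) was called at 6 h against ZT9, and none when adjusted over its list alone. In limma, 1847 genes had an unadjusted p under 0.05. This depends on the control, as the clock hour of the 6 h glands is not given: against ZT3, limma called Arntl (log2 change -2.751, adjusted p = 0.0103), Npas2 (-2.207, 0.0422), Per2 (2.377, 0.0282) and Per3 (2.462, 0.0396). Against ZT9, the core clock list had a median log2 change of 0.11 (adjusted p = 0.597) and the PAR bZIP list -0.43 (adjusted p = 0.193). The activator Arntl was 0.829 ± 0.0366 at ZT9 and 0.954 ± 0.132 at 6 h, and the repressor Per2 was 6.80 ± 2.95 at ZT9 and 5.96 and 6.81 in the libraries at 6 h. Dbp was 198 ± 118 and 90.9 ± 5.82. Log2 changes of other clock genes included -0.67 (Nr1d1), -0.61 (Ciart), -0.60 (Nfil3), -0.36 (Per3), -0.26 (Hlf), -0.23 (Cry1), -0.19 (Cry2), -0.11 (Bhlhe41), 0.11 (Tef), 0.12 (Bhlhe40), 0.15 (Csnk1e), 0.18 (Per1), 0.18 (Nr1d2), 0.24 (Csnk1d), 0.25 (Clock), 0.28 (Rora) and 0.40 (Npas2).

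Besides p53 targets, 5 of the 29 lists passed at 6 h with the preset correlation and none of these with an estimated one (adjusted p = 0.997 for each). All 15 genes of cholesterol synthesis were higher (median log2 change 0.93, adjusted p = 4.9e-05), with none called; Insig1, which restrains that pathway, was 66.1 ± 32.5 at ZT9 and 200 ± 89.3 at 6 h. All 12 macrophage markers (0.57, adjusted p = 0.0137) and all 10 inflammatory cytokine genes (0.91, adjusted p = 0.0156) were higher with none called and 1 of each list rising adjusted over the list alone (Cd14 and Icam1); Icam1, an adhesion molecule, was 4.24 ± 1.03 and 30.0 ± 12.1. All 9 mitochondrial transcripts (-0.34, adjusted p = 0.0146) and all 7 adipocyte markers (-0.77, adjusted p = 0.0474) were lower with none called. Replicate 2 at 6 h held more lymphocyte and blood RNA than replicate 1: Igkc was 3891 and 156, Cd4 8.25 and 0.0858 and Hba-a1 141 and 26.1. Without replicate 2 at 6 h the adjusted p was 0.125 for macrophages and 0.410 for cytokines, and without ZT9 replicate 2 it was 0.296 for both, 0.124 for mitochondrial transcripts and 0.677 for adipocytes. Against ZT3 the cytokine call was lost (0.176), and mitochondrial transcripts (0.888) and adipocytes (0.716) were reversed and not past. The Y term ended the calls of mitochondrial transcripts (0.115) and adipocytes (0.269), and the Amy1 term those of macrophages (0.169) and mitochondrial transcripts (0.717). The adipocyte call was also lost under median-of-ratios scaling (0.114), quantile normalization (0.138), a pseudocount of 0.1 (0.0647), no filter (0.107) and a mean FPKM of at least 5 (0.0867), without replicate 1 at 6 h (0.266) or ZT15 replicate 2 (0.0646), and against the mean of 3 control times (0.338). The mitochondrial call was lost with no filter (0.0712) and against that mean (0.504). Igkc, Cd4, Hba-a1, Insig1 and Icam1 were chosen after their values were seen. Of the other 23 tested lists, with adjusted p from 0.0881 to 0.997, none held a called gene except the plasma cell list, and 3 glucocorticoid response genes rose adjusted over the list alone. Among these lists, granular convoluted tubule genes were higher in 16 of 17 cases (median 2.09, adjusted p = 0.222). That list passed camera under median-of-ratios scaling (0.0339), while the Y term reversed its direction (0.992). Amy1, the only parotid product kept, had a log2 change of 6.07 at 6 h and 1.89 at 24 h, not called.

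Against ZT9, 78 genes were called at 6 h, 72 higher and 6 lower, while the median log2 change of all kept genes was 0.12. The count was 3 with only the compared libraries, 35 with a term for Y-linked transcripts, 12 without irradiated replicate 1, which leaves libraries with Xist alone, and 9 without irradiated replicate 2; all 78 genes kept their direction under each of these. With Amy1 as a term, 15 were called, and with quantile normalization 48. On simulated data with independent noise and a log2 change of 2, 86% of changed genes were recovered in this comparison. The 6 h files share their gene order with ZT3 and not with ZT9. Processing in separate sets therefore cannot be told apart from irradiation in the comparison with ZT9. Against ZT3, another clock time, 74 of the 78 genes kept their direction and 52 were still called.

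At 24 h the p53 response was still present. Against ZT3, 16 of the 30 targets rose, 26 when adjusted over the list alone, and 29 were higher, with a median log2 change of 1.69 (adjusted p = 4.1e-27; adjusted p = 0.0352 with an estimated correlation). Cdkn1a went from 1.44 ± 0.839 to 55.3 ± 3.41, Ccng1 from 35.9 ± 2.48 to 236 ± 12.9, Phlda3 from 7.42 ± 0.0558 to 58.5 ± 3.58 and Sulf2, a heparan sulfatase, from 4.93 ± 0.822 to 25.9 ± 5.47. Eda2r (log2 change 3.31) and Psrc1 (2.92) were also among the largest rises. Ephx1, an enzyme that detoxifies epoxides, went from 39.6 ± 2.44 to 325 ± 91.8. Sumo2 went from 9.36 ± 0.606 to 99.1 ± 7.72, a gene with processed pseudogene copies, and Rn7s1, a signal recognition particle RNA, was listed at 0 in both ZT3 libraries with a mean of 8.49 ± 3.42 at 24 h. Glrx, a glutaredoxin, fell from 16.6 ± 1.47 to 4.69 ± 0.557 and Sult1c1, a sulfotransferase of the acinar list, from 7.32 ± 1.29 to 0.767 ± 0.487.

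Clock genes stood higher at 24 h than at ZT3. The clock hour of the 24 h glands is not given, so an effect of the hour cannot be told apart from one of radiation. The Period genes, repressors in the clock, rose: Per2 from 0.420 ± 0.0727 to 9.52 ± 4.06, Per3 from 2.82 ± 1.73 to 21.9 ± 9.51 and Per1 from 6.76 ± 0.226 to 36.2 ± 19.2. In unirradiated glands Per2 was 11.5 ± 1.47 at ZT15, and at ZT9 Per3 was 25.0 ± 6.39 and Per1 22.9 ± 2.43. These 3 of the 18 core clock genes were called over all genes. Adjusted over the list alone, 11 rose and 2 fell. The list had 16 genes higher and a median log2 change of 0.74 (adjusted p = 0.00272; adjusted p = 0.350 with an estimated correlation). The activators Arntl and Npas2 were lower without being called, while Clock was 8.06 ± 0.0891 and 8.68 ± 2.76: Arntl was at 12.5 ± 4.36 and 4.24 ± 1.51 (adjusted p = 0.0979) and Npas2 at 8.23 ± 4.29 and 2.28 ± 0.642 (adjusted p = 0.119). Uncalled log2 changes included 1.77 (Ciart), 1.21 (Cry2), 1.21 (Nr1d2), 0.76 (Bhlhe41), 0.74 (Bhlhe40), 0.74 (Cry1), 0.71 (Rora), 0.57 (Nr1d1), 0.45 (Csnk1e), 0.23 (Csnk1d) and 0.07 (Clock). Of the PAR bZIP genes, whose list had an adjusted p of 0.345, none was called and 2 rose and 1 fell adjusted over the list alone: Tef was 22.7 ± 9.49 at ZT3 and 101.2 ± 40.3 at 24 h, Dbp 6.21 ± 3.31 and 49.2 ± 38.4, Nfil3 9.72 ± 2.67 and 4.01 ± 0.520, and Hlf 0.408 ± 0.233 and 0.999 ± 0.428. The calls of Per1 and Per3 were lost with median-of-ratios scaling (adjusted p = 0.0874 and 0.0797) and those of all 3 Period genes with a term for Y-linked transcripts (adjusted p = 0.0968 for Per1, 0.0754 for Per2 and 0.130 for Per3). Without replicate 2 at 24 h, the adjusted p was 0.0814 for Per1, 0.177 for Per2 and 0.238 for Per3, and without replicate 1 it was 0.0138, 0.0448 and 0.0913.

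**Figure D2:**
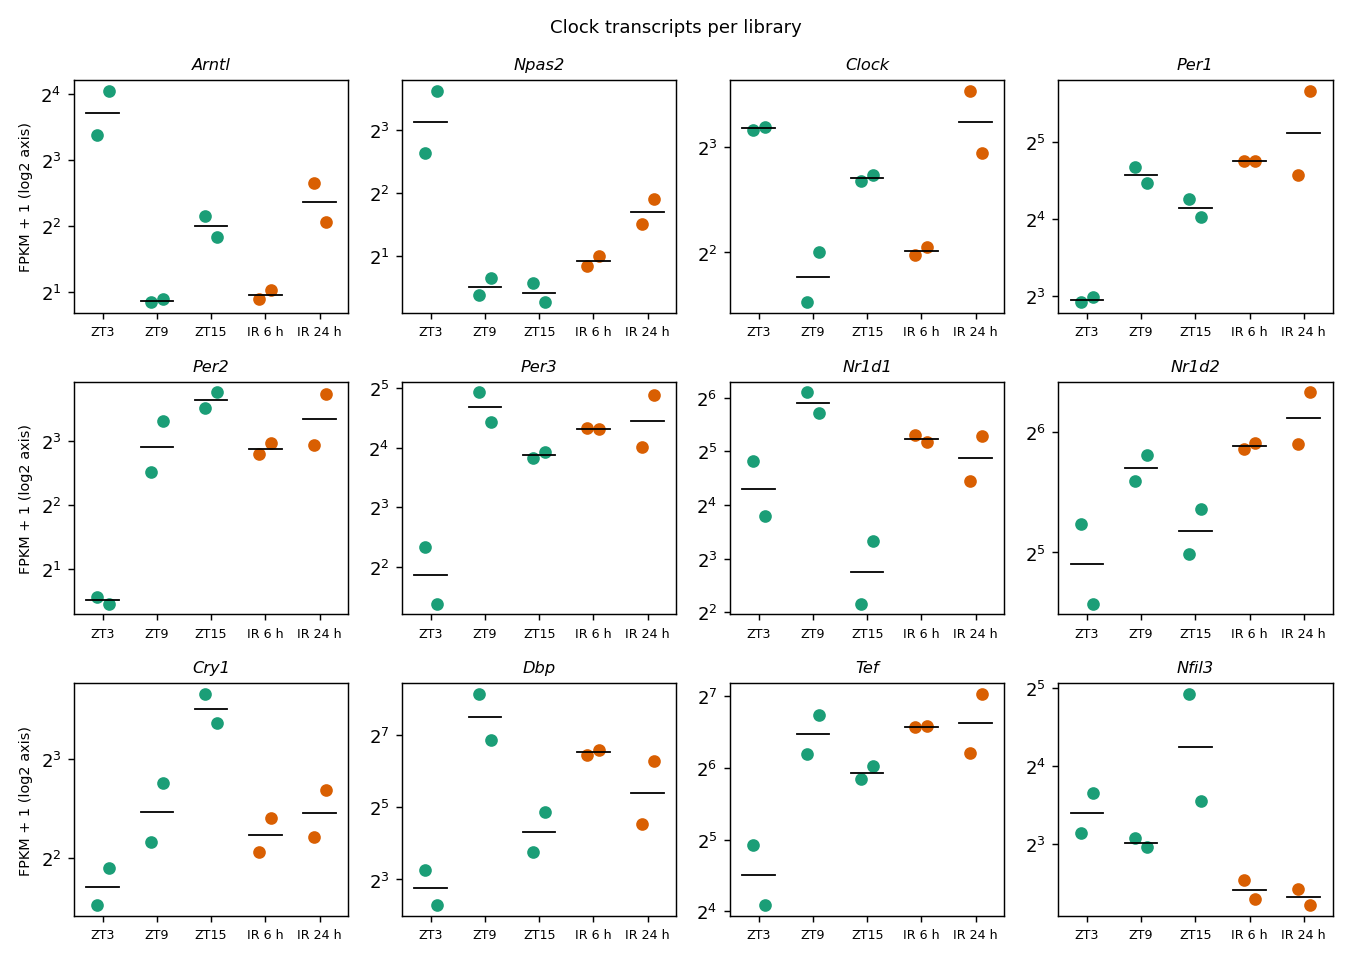
FPKM + 1 (log2 axis) of clock transcripts in each library, by group; points are libraries (green, unirradiated; orange, irradiated) and lines are means on the log2 scale. Arntl was 12.5 at ZT3, 0.829 at ZT9, 3.01 at ZT15, 0.954 at 6 h and 4.24 at 24 h.

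Genes induced by glucocorticoids were higher at 24 h, 11 of 12 with a median log2 change of 0.88 (adjusted p = 0.00208; adjusted p = 0.196 with an estimated correlation). Zbtb16, a transcription factor, rose from 2.40 ± 0.0622 to 9.58 ± 2.13 and was the only member called over all genes, while 8 rose and 1 fell adjusted over the list alone. The metallothionein Mt2, chosen after its values were seen, was 70.7 ± 38.6 and 303 ± 76.5. Both cold-inducible genes were higher and rose adjusted over the list alone: Rbm3 was 94.9 ± 5.67 and 193 ± 17.7, and Cirbp 73.2 ± 15.5 and 133 ± 5.48. In unirradiated glands, 4 glucocorticoid response genes (Fkbp5, Tsc22d3, Zbtb16 and Sgk1) changed across the day by the F test adjusted over the list alone. The medians of that list against ZT3 were -0.02 at ZT9 and 0.03 at ZT15. The clock hour of the 24 h glands is not given.

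Transcripts of the granular convoluted tubule, the androgen-dependent duct segment that makes growth factors and kallikreins, were lower at 24 h than at ZT3 in 16 of 17 cases, with a median log2 change of -4.51 (adjusted p = 3.1e-14; adjusted p = 0.350 with an estimated correlation) and none called. Egf was 7722 and 11262 in the ZT3 libraries and 811 and 66.1 at 24 h, the higher value in the library with Y-linked transcripts. Both ZT3 libraries had Y-linked transcripts and 1 of the 24 h libraries did. With a term for Y-linked transcripts the list was still lower in camera at the preset correlation (adjusted p = 5.7e-28). The same held for unirradiated ZT9 against ZT3 (adjusted p = 2.4e-17). The exception was Klk1, at 3571 ± 861 and 10342 ± 2683. Egf and Klk1 were chosen after their values were seen.

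Several lists of immune, blood, stromal and dividing cells were lower at 24 h than at ZT3, with none of their genes called. All 13 T cell (median log2 change -1.55, adjusted p = 6.2e-07) and all 13 B cell markers (-1.38, adjusted p = 1.2e-05) were lower, as were 8 of 9 plasma cell (-2.01, adjusted p = 6.2e-06), 5 of 8 neutrophil (-0.49, adjusted p = 0.0291) and all 5 blood cell transcripts (-1.36, adjusted p = 9.0e-05). Cd3e, of the T cell receptor complex, was 3.65 ± 4.83 at ZT3 and 0.0172 ± 0.0243 at 24 h, and Jchain, of secreted antibodies, 625 ± 234 and 37.6 ± 4.25. All 10 fibroblast and matrix genes (-0.84, adjusted p = 6.2e-06) were lower, as were 20 of 23 proliferation genes (-0.56, adjusted p = 1.0e-05) and 7 of 9 myoepithelial and basal genes (-0.48, adjusted p = 0.000744). Top2a, a topoisomerase of dividing cells, was 2.11 ± 2.31 and 0.0715 ± 0.0517. Cd3e, Jchain and Top2a were chosen after their values were seen. None of these 8 lists passed with an estimated correlation; the adjusted p was 0.466 for T cells, 0.473 for B cells, 0.350 for plasma cells, 0.621 for neutrophils, 0.350 for blood cells, 0.350 for fibroblasts, 0.577 for proliferation and 0.350 for myoepithelial cells. Cd3e was 0.231 in ZT3 replicate 1 and 7.06 in ZT3 replicate 2, so the ZT3 libraries differed in lymphocyte RNA. Unirradiated glands at ZT9 also had lower medians than at ZT3 for plasma cells (-1.61), B cells (-1.29), T cells (-0.86), neutrophils (-0.63) and myoepithelial cells (-0.58). Their medians were higher for proliferation (0.54), blood cells (0.49) and fibroblasts (0.47). Of the former lists, only myoepithelial cells passed camera at ZT9 with the preset correlation (adjusted p = 0.0481). At ZT15 the medians against ZT3 were -0.27 for plasma cells and -0.96 for myoepithelial cells. They were higher for T cells (0.42), B cells (0.90) and neutrophils (0.82). Medians below ZT3 were thus also seen without irradiation, but for T cells, B cells and neutrophils at ZT9 alone.

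**Figure D3:**
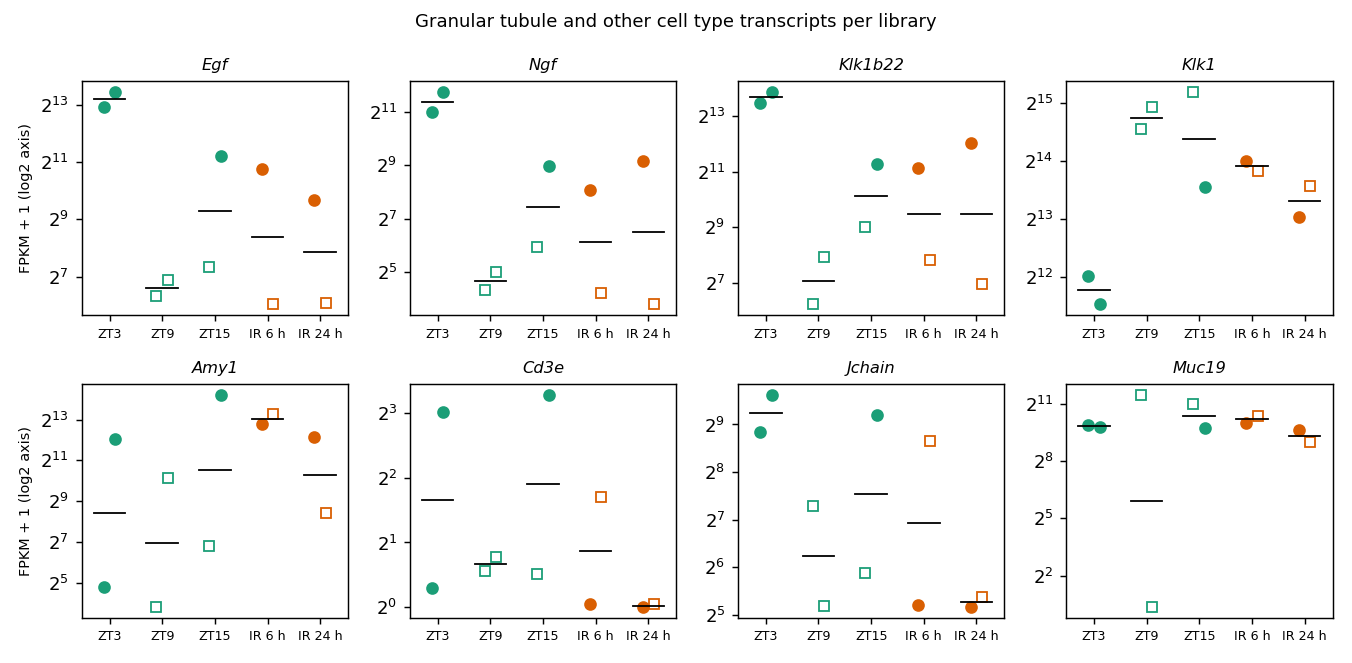
FPKM + 1 (log2 axis) of granular tubule, amylase, lymphocyte and mucin transcripts in each library, by group (green, unirradiated; orange, irradiated); filled circles are libraries with Y-linked transcripts, open squares those without, and lines are means on the log2 scale. Egf was 79.6 and 117 in the ZT9 libraries and 7722 and 11262 in the ZT3 libraries.

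Of the unfolded protein response, the chaperones and foldases of the endoplasmic reticulum, 14 of 15 were lower (median log2 change -0.53, adjusted p = 2.1e-10, or 0.196 with an estimated correlation), with none called. The chaperone Hspa5, chosen after its values were seen, was 377 ± 130 and 204 ± 2.77. In unirradiated glands this list was also lower at ZT9 than at ZT3, with a median of -0.80, and its median at ZT15 was -0.06. Of the 18 acinar secretory products, 11 were lower (-0.18, adjusted p = 0.00842; adjusted p = 0.473 with an estimated correlation) and Sult1c1 fell. The acinar list lost its call under median-of-ratios scaling (adjusted p = 0.163), quantile normalization (0.268) and the Amy1 term (0.0803), and without ZT3 replicate 1 (0.0533) or replicate 1 at 24 h (0.233). The neutrophil list lost its call under median-of-ratios scaling (0.390), quantile normalization (0.268), the Y term (0.237) and the B cell term (0.304, with its direction reversed), and without ZT3 replicate 2 (0.573) or replicate 2 at 24 h (0.0844). Calls were also lost without ZT3 replicate 2 for cholesterol synthesis (0.227), at a mean FPKM of at least 5 for glucocorticoid response (0.0577) and proliferation (0.111), against the mean of 3 control times for myoepithelial cells (0.367), and with the B cell term for proliferation (0.0547). Of 15 cholesterol synthesis genes 12 were lower (-0.49, adjusted p = 0.000114; adjusted p = 0.473 with an estimated correlation). The remaining 14 tested lists had an adjusted p from 0.0702 to 0.962 and, apart from the PAR bZIP list above, comprised DNA repair, fluid and ion secretion, duct cells, macrophages, interferon response, inflammatory cytokines, heat shock, immediate early genes, endothelial cells, adipocytes, skeletal muscle, sex-linked genes and mitochondrial transcripts, none with a called gene. Macrophage markers were higher in 9 of 12 cases (median 0.41), and endothelial markers were higher in 4 and lower in 4. Adjusted over the list alone, 1 adipocyte gene rose, and 1 gene each of the inflammatory cytokine and myoepithelial lists fell.

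Against ZT3, 75 genes were called at 24 h, 70 higher and 5 lower, and the median log2 change of all kept genes was 0.21. With median-of-ratios scaling, which removes that shift, 34 were called, 26 higher and 8 lower; 19 were called with a term for Y-linked transcripts, 0 with only the compared libraries (3379 at an unadjusted p under 0.05 in limma) and 842 against the mean of the 3 control times, while all 75 genes kept their direction under each of these. The count was 19 without ZT3 replicate 1, 12 without ZT3 replicate 2, 19 without replicate 1 at 24 h and 11 without replicate 2 at 24 h. On simulated data with independent noise and a log2 change of 2, 84% of changed genes were recovered in this comparison.

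The groups compared at 6 h and 24 h share no library, and 35 genes rose in both, against 0.332 if the calls were independent. They are not fully independent, since both comparisons take the spread of each gene from the same fit over all 10 libraries. No gene fell in both. Of the 78 genes called at 6 h, 68 changed in the same direction at 24 h and 61 of them with an unadjusted p under 0.05. Across all 15161 genes, which are not independent replicates, the log2 changes had a Pearson correlation of -0.12 and a Spearman correlation of -0.01. The change at 24 h minus the change at 6 h differed for 3 genes, all lower: Gm27913 was 55.1 and 64.4 at 6 h and listed at 0 in the other 8 libraries, Gm20305 was 49.7 and 52.7 at 6 h and listed at 0 in the other 8, and Gm14391 was 6.23 and 8.17 at 6 h, 0.0933 and 0.399 at ZT9, 0.442 and 0.351 at 24 h and 12.0 and 6.18 at ZT3. These predicted genes were named after their values were seen. On simulated data with independent noise, 56% of genes with a log2 change of 2 were recovered for this contrast.

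Over the day, the clock genes of unirradiated glands followed different courses. Arntl was 12.5 ± 4.36 at ZT3, 0.829 ± 0.0366 at ZT9 and 3.01 ± 0.603 at ZT15, and its partner Clock was 8.06 ± 0.0891, 2.45 ± 0.802 and 5.55 ± 0.186. Nr1d1, a repressor of Arntl, was 20.0 ± 10.0, 59.6 ± 11.5 and 6.29 ± 3.99, and Dbp was 6.21 ± 3.31, 198 ± 118 and, in the ZT15 libraries, 12.5 and 28.1. Per2 was 0.420 ± 0.0727, 6.80 ± 2.95 and 11.5 ± 1.47, and Cry1, a later repressor, 2.298 ± 0.604, 4.605 ± 1.59 and 10.4 ± 1.66. By the F test none of the core clock or PAR bZIP genes was called over all genes (smallest adjusted p = 0.0885, Arntl and Per2), while adjusted over the list alone 12 of 18 core clock genes (among them Arntl, Clock, Npas2, Per1, Per2, Per3, Cry1, Cry2, Nr1d1, Ciart and Bhlhe41) and all 4 PAR bZIP genes changed. Adjusted over the 22 clock genes together, Nfil3 did not pass (adjusted p = 0.0604). Core clock genes not past it had adjusted p-values over the same 22 that included 0.0576 (Nr1d2), 0.118 (Bhlhe40), 0.280 (Csnk1d), 0.328 (Csnk1e) and 0.524 (Rora).

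In pairs, the core clock list adjusted alone had 9 genes higher and 3 lower at ZT9 than at ZT3, 6 higher and 3 lower at ZT15 than at ZT3, and 4 higher and 2 lower at ZT15 than at ZT9. All 17 granular tubule genes changed across the day adjusted over the list alone, 16 of them lower at ZT9 than at ZT3 with a median log2 change over the list of -6.60 (adjusted p = 1.7e-09; adjusted p = 0.754 with an estimated correlation); both ZT3 libraries had Y-linked transcripts and neither ZT9 library did. Of the 29 lists, 11 passed for ZT9 against ZT3, 8 for ZT15 against ZT3 and 10 for ZT15 against ZT9, and none with an estimated correlation (smallest adjusted p = 0.693, 0.241 and 0.868). Interferon response genes were higher at ZT9 than at ZT3 in 17 of 17 cases (0.78, adjusted p = 3.8e-06; adjusted p = 0.754 with an estimated correlation), and 9 of 10 heat shock genes were higher at ZT15 than at ZT3 (0.55, adjusted p = 0.000314; adjusted p = 0.241 with an estimated correlation).

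Over all genes, 3 were called by the F test across the day, all predicted genes: Gm19810, listed at 0 in both ZT3 libraries with 7.69 ± 1.42 at ZT9 and 15.8 ± 5.22 at ZT15; Gm10320, at 47.1 ± 18.1, 4.58 ± 0.171 and 2.72 ± 0.826; and Gm5963, listed at 0 at ZT3 and ZT9 with 4.83 ± 0.731 at ZT15. Gm19810 was also listed at 0 in all irradiated libraries, whose files share their gene order with those of ZT3. In pairs, 1 gene was called for ZT9 against ZT3 (Gm19810) and 3 for ZT15 against ZT3 (the 3 above), and for ZT15 against ZT9 limma called 0 with 1106 at an unadjusted p under 0.05. Genes with the smallest p but not past the threshold were Arntl and Gm10320 (both adjusted p = 0.0536), Slc7a5 (0.0536) and Slc28a3 (0.0758) for ZT9 against ZT3, Per2 (0.0652) and Gm15459 (0.0699) for ZT15 against ZT3, and Gm5963 (0.0624), Gm12112 (0.249), Folh1, Gm29103 and Ighv5-12 (0.521 each) for ZT15 against ZT9. Without ZT9 replicate 1 the F test called 10 genes and ZT15 against ZT9 called 13, and without ZT3 replicate 2 or ZT9 replicate 2 the F test called 0; with a term for Y-linked transcripts it called 0. On simulated data with independent noise, 80% of genes with a log2 change of 2 at ZT9 were recovered by the F test.

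The CUT&Tag lists held 31014 and 19746 summits for Bmal1, 9627 and 38363 for Nr1d1 and 49295 and 10352 for Dbp. Of the shorter list of a target, 38.7% of summits lay within 200 bp of a summit of the longer list for Bmal1, 37.8% for Nr1d1 and 82.2% for Dbp, where shifted lists gave means of 0.522%, 0.638% and 0.817%. For Bmal1 and Nr1d1 some lists of different targets overlapped more: 79.6% of Bmal1 list 1 lay within 200 bp of a summit of Nr1d1 list 2, and 70.4% of Nr1d1 list 1 within 200 bp of Bmal1 list 2, while 10.9% of Bmal1 list 1 lay within 200 bp of Nr1d1 list 1. Dbp list 2 overlapped Dbp list 1 more than any other list. With the 9584 highest-scoring summits of each list, the same-target pairs overlapped by a mean of 39.9% and the pairs of different targets by 41.4%, and 1 of the 6 lists (Dbp list 2) had its closest partner in its own target; 10 of the 15 ways to pair the lists gave a mean as high as the real one. Regions found in both lists numbered 7625 for Bmal1, 3624 for Nr1d1 and 8468 for Dbp, and 1895 were shared by the 3 targets. Of the Nr1d1 regions 71.6% were shared with Bmal1 and 62.8% with Dbp, and of the Bmal1 regions 47.5% were shared with Dbp, where shifted regions gave means of 0.134%, 0.151% and 0.148%.

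**Figure D4:**
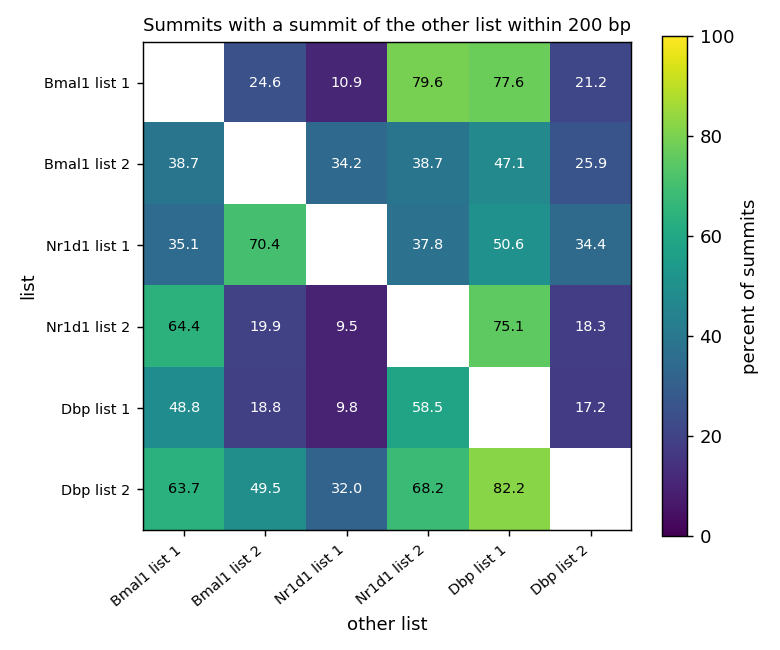
Percent of the summits of each list (vertical axis) with a summit of the other list (horizontal axis) within 200 bp, from 0 to 100 on the color scale. Bmal1 list 1 overlapped Nr1d1 list 2 by 79.6% and Bmal1 list 2 by 24.6%.

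In mm10, all 6 lists had a summit within 1 kb of an end of Per1, Per3, Nr1d1, Nr1d2, Ciart, Dbp and Tef. At Ciart, Dbp and Tef, however, no region was found in both Dbp lists. At Dbp (chromosome 7, 45705100 to 45710203), which Bmal1 is known to activate, the Bmal1 summits lay at 45704940 and 45704933. At Per1 (chromosome 11, 69095108 to 69109965) they lay at 69095035 and 69094901, and at Nr1d1 (chromosome 11, 98767932 to 98775377) at 98775369 and 98775346. Summits of 5 lists lay at Per2, Cry2, Bhlhe40 and Bhlhe41, of 4 lists at Cry1, Csnk1e and Nfil3, of 3 at Clock and Csnk1d, and of 1 at Npas2 and Hlf. A summit of a long list at a gene end was common. Of 21887 protein-coding genes, 8983 had one in Bmal1 list 1, 9468 in Nr1d1 list 2 and 9772 in Dbp list 1. In the other lists the number was 1450 to 3241. No list had a summit within 1 kb of an end of Arntl or Rora. Only the outermost ends of each gene were examined, so this does not cover start sites inside a gene. Protein-coding genes with a region of both lists at an end numbered 2812 for Bmal1, 1245 for Nr1d1 and 2882 for Dbp of 21887, against means of 250, 121 and 280 for shifted regions.

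The highest-scoring regions were largely not at clock genes. A region on chromosome 16 inside Cmss1 and Filip1l (at 57391520 for Bmal1, 57391531 for Nr1d1 and 57391530 for Dbp) and a region on chromosome 15 between genes nearest Ly6c2 (75086869, 75086837 and 75086869) were among the top 5 of each target. The other Bmal1 regions lay 11 bp from an end of Arhgap12 (chromosome 18, 6136109), 134 bp from an end of Cdk4 (chromosome 10, 127063401) and inside Tusc3 (chromosome 8, 39153004). The other Nr1d1 regions lay far from genes on chromosome 2 (98662700), chromosome 11 (109011839, nearest Axin2) and chromosome 3 (5860693, nearest Pex2). The other Dbp regions lay inside Aida (chromosome 1, 183299355), inside Zbtb20 (chromosome 16, 42947285) and on chromosome 4 at 151044883, inside the predicted gene Gm38529 and beside the end of Per3 at 151044707. Without a control sample or read depths, regions where reads pile up in any library cannot be told from binding.

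Genes that changed after irradiation carried regions about as often as other genes. For Bmal1, 22.9% of the 70 called genes at 6 h that were found in the table had a region at an end, against 19.6% of all 14286 genes (Fisher's exact p = 0.453), and 22.1% of 68 at 24 h (exact p = 0.645). For Nr1d1 the shares were 12.9% at 6 h and 10.3% at 24 h against 8.77% (exact p = 0.206 and 0.665), and for Dbp 15.7% and 17.6% against 20.0% (exact p = 0.454 and 0.761). None of the 3 genes called across the day had a region, too few to test. These p-values are unadjusted over 9 tests, each with an adjusted p of 1, and they do not show that the shares are equal. With an unadjusted p under 0.05 as the rule for change, chosen after seeing the data, 24.1% of the 1865 genes changing across the day had a Bmal1 region against 19.6% of all (odds ratio 1.36, exact p = 2.7e-07; p = 0.0034 against random lists matched on FPKM). The odds ratio was 1.37 for Nr1d1 (exact p = 0.000156; matched p = 0.0294) and 1.25 for Dbp (exact p = 0.000216; matched p = 0.129). With regions in either list the excess over matched lists was gone: 1217 such genes had a Bmal1 region against a matched mean of 1218 (permutation p = 0.960 over the matched random lists), and that p was 0.724 for Nr1d1 and 0.521 for Dbp. Within 5 kb of a gene end, for regions in both lists, the permutation p was 0.0002 for Bmal1, 0.0504 for Nr1d1 and 0.216 for Dbp.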

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

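All tests of explanations below were chosen only after the results were seen. The change at 24 h minus the change at 6 h differed for 3 genes, named with their values above. By list, with the preset correlation, it was lower for granular tubule (adjusted p = 2.23e-10), cholesterol synthesis (6.2e-09), unfolded protein response (9.98e-06), plasma cells (2.07e-05), T cells (0.000409), p53 targets (0.00104), blood cells (0.00113), fibroblasts and B cells (0.0026 each), proliferation (0.00377), inflammatory cytokines (0.00456), neutrophils (0.00674) and myoepithelial cells (0.0382). It was higher for the core clock (0.00195), mitochondrial transcripts (0.00377), duct cells (0.0227) and PAR bZIP genes (0.0396). None passed with an estimated correlation (smallest adjusted p = 0.400), and the controls of the 6 h and 24 h groups differ in Y-linked transcripts and in gene order.

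Granular tubule transcripts were higher at ZT3 than at ZT9 by a median log2 of 6.60. Sex of the animals likely accounts for part of this: within the groups holding both kinds of library, those with Y-linked transcripts were higher by a mean of 3.69. Processing in 2 sets, as the gene orders would have it, was not decided. Among libraries without Y-linked transcripts, the irradiated ones differed from ZT9 by -0.0701, but they differ in irradiation as well as in gene order. An effect of irradiation could therefore hide one of the set. An added effect of time of day cannot be told apart from one of the set, since only 1 control library outside ZT3 had Y-linked transcripts. That ZT15 library was lower than ZT3 by a median log2 of 2.27 (-2.27), a difference left with Y-linked transcripts present on both sides. Its file has the other gene order from those of ZT3. Recorded sex and same-sex groups at each time, processed together, would separate these.

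The Period genes were higher at 24 h than at ZT3 by a mean log2 of 2.53. That mean was 2.37 with a term for Y-linked transcripts and 2.304 with median-of-ratios scaling, although calls were lost under both. With the Y term, which leaves 4 residual degrees of freedom, Per1 went from 2.16 (standard error 0.316) to 1.94 (0.287). Per2 went from 2.83 (0.332) to 2.71 (0.364) and Per3 from 2.597 (0.377) to 2.47 (0.418). With scaling, Per1 went to 1.91 (0.321) and Per3 to 2.36 (0.385) as the changes shrank. The scaling factors were 0.935 and 0.949 at ZT3 and 1.15 and 1.12 at 24 h, too close to remove such a change, so that result was fixed by their size. Replicate 1 at 24 h, with Y-linked transcripts like both ZT3 libraries, was alone higher than ZT3 by a mean of 2.07. These values speak against sex or this scaling as the whole cause, though the same-sex value rests on 1 library at 24 h. Collection at another clock hour than ZT3 could give the same changes and cannot be told apart from an effect of radiation: 5 of 22 clock genes lay outside the range of the 6 control libraries in both libraries at 24 h, against 26.2% of all genes. The hour of irradiation and unirradiated glands taken beside the irradiated ones would decide it.

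Except for Dbp list 2, the summit lists resembled a list of another target more than the second list of their own. With equal numbers of summits the same-target pairs still did not stand above the others (-1.54 points, with 10 of 15 pairings as high). Unequal numbers alone thus did not account for the pattern. The cut took all of Nr1d1 list 1 but part of each other list, so depth and stringency were not made equal. Bmal1 list 1 still overlapped Nr1d1 list 2 by 66.8% and Dbp list 1 by 56.9%. The shorter Bmal1 list 2 and Nr1d1 list 1 overlapped by 49.0%, while Dbp list 2, also shorter, was closest to Dbp list 1. Exchanged labels of the first Bmal1 and first Nr1d1 lists would put same-target pairs 19.7 points above the others, but that exchange was picked as the best of 15 pairings. With it, 5 of the 6 lists would be closest to their own target. Dbp list 1 overlapped Nr1d1 list 2 (60.7%) more than Dbp list 2 (54.6%). The longest lists, Bmal1 list 1, Nr1d1 list 2 and Dbp list 1, had 1.57%, 1.90% and 1.93% of summits on chromosome X. In the other lists that share was 0.343% to 0.850%, a split that runs across targets. The clock genes ran the way of the labels among the 9584 highest-scoring summits of each list. Of the 9 clock genes with a summit in both first lists, 8 ranked higher in Bmal1 than in Nr1d1 (exact sign test p = 0.0391). Ranks were 33 and 7241 for Per3, the widest gap, 38 and 75 for Nr1d2, and 796 and 557 for Nr1d1, the exception. In the second lists it was 12 of 13 (exact sign test p = 0.00342). These tests count genes, which are not independent, within 1 list per target. Their p-values do not measure the spread between libraries. Overlap and ranks point opposite ways. An exchange cannot be told apart from a difference in quality between single libraries or between the longer and shorter lists. Nor can it be told apart from open chromatin shared by all targets.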

How the results depend on the processing

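The terms for Y-linked transcripts, Amy1 and B cells, the wider summit distance and the unadjusted p were chosen only after the results were seen. Where no cause is named, the cause was not tested.

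The 78 genes called at 6 h became 48 with quantile normalization, 3 with only the groups compared (fewer samples), 35 with the Y term, 15 with the Amy1 term, 12 without irradiated replicate 1, 9 without irradiated replicate 2, 72 without ZT15 replicate 2, 120 against ZT3 and 154 against the mean of 3 control times. The 75 at 24 h became 133 with no filter, 34 with median-of-ratios scaling, 36 with quantile normalization, 0 with only the groups compared, 19 with the Y term, 36 with the B cell term, 19 and 12 without ZT3 replicates 1 and 2, 19 and 11 without irradiated replicates 1 and 2, 70 without ZT15 replicate 2, 842 against the mean of 3 control times and 157 with the Y term added to that.

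The 3 genes across the day became 7 with a pseudocount of 0.1, 24 with no filter, 0 with a mean FPKM of at least 5 (fewer genes tested), 1 with quantile normalization, 0 with only the groups compared, 0 with the Y term, 0 with the Amy1 term, 1 and 0 without ZT3 replicates 1 and 2, 10 and 0 without ZT9 replicates 1 and 2, and 1 without ZT15 replicate 2. For ZT9 against ZT3 the 1 gene became 8 with a pseudocount of 0.1, 17 with no filter, 0 with a mean FPKM of at least 5, 4 with median-of-ratios scaling, 2 with quantile normalization, 4 with robust moderation, 17 with only the groups compared, 0 with the Y term, 0 with the Amy1 term, 2 with the B cell term, 2 and 0 without ZT3 replicates 1 and 2, 9 and 0 without ZT9 replicates 1 and 2, and 4 without ZT15 replicate 2. With the replicate number as a term it stayed at 1, but Gm19810 was lost (adjusted p = 0.0780) and Gm10320, lower at ZT9, was called (0.0399).

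For ZT15 against ZT3 the 3 genes became 7 with a pseudocount of 0.1, 21 with no filter, 1 with a mean FPKM of at least 5, 6 with quantile normalization, 7 with the replicate number as a term, 0 with only the groups compared, 1 with the Y term, 5 and 0 without ZT3 replicates 1 and 2, and 1 and 1 without ZT15 replicates 1 and 2. For ZT15 against ZT9 the 0 became 1 with a pseudocount of 0.1, 10 with no filter and 13 without ZT9 replicate 1. The 3 genes differing between 24 h and 6 h became 0 with a pseudocount of 0.1, 7 with no filter, 0 with a mean FPKM of at least 5, 6 with the B cell term, 5 without ZT3 replicate 1 and 8 without ZT9 replicate 1.

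Of 2481 gene and setting combinations, 2239 were the same, 209 weaker, 27 stronger and 6 reversed. The reversals came with ZT3 as the control for 6 h: log2 changes of 0.23 for Slc7a5, 0.0182 for Gpt2, -2.751 for Arntl, -2.207 for Npas2, 2.38 for Per2 and 2.46 for Per3. These follow the difference between ZT9 and ZT3 in the same genes.

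With an estimated correlation the lists past the threshold went from 6 to 1 at 6 h, 15 to 1 at 24 h, 11 to 0 for ZT9 against ZT3, 8 to 0 for ZT15 against ZT3, 10 to 0 for ZT15 against ZT9 and 17 to 0 for the difference between 24 h and 6 h. At 6 h, 10 passed without ZT9 replicate 1 and 3 without ZT9 replicate 2. Without ZT9 replicate 2, 3 passed for ZT9 against ZT3 (16 without ZT15 replicate 2), 2 for ZT15 against ZT9 and 8 for the difference. For ZT15 against ZT3, 17 passed without ZT15 replicate 1, and for ZT15 against ZT9, 3 without ZT15 replicate 2. With the Y term, 5 passed for ZT15 against ZT9 and 10 for the difference. The correlation of changes at 6 h and 24 h went from -0.12 to -0.11 with a pseudocount of 0.1, -0.18 with a mean FPKM of at least 5 and -0.0794 with the Y term.

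The overlap of same-target lists was 30.8% (Bmal1), 29.6% (Nr1d1) and 67.2% (Dbp) within 100 bp, 38.5%, 37.6% and 84.9% for the higher-scoring part of each list and 42.4%, 41.2% and 87.5% at the wider distance. That part gave 3875, 1800 and 4384 regions and 1673, 634 and 1633 genes with a region at an end; summits in either list gave 9163, 9566 and 9812 genes. Within 100 bp, 57.8% of Nr1d1 regions were shared with Bmal1, 50.4% with Dbp, and 38.6% of Bmal1 regions with Dbp; for the higher-scoring part these were 66.3%, 56.1% and 42.4%. With an unadjusted p for changed genes, the odds ratios passed for Bmal1 at 6 h (1.16) and 24 h (1.18), Nr1d1 at 24 h (1.24) and Dbp at 24 h (1.31), none of them outside lists matched on FPKM. With regions in either list, Bmal1 at 6 h stood just outside them (1178 genes against 1105 to 1176, permutation p = 0.0410), and the other targets and 24 h did not.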

Other observations

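The gene groups below were drawn up only after the values were seen and hold the genes that prompted them, so no test of them is given.

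Ribosomal protein genes stood higher at 24 h than at ZT3, all 76 of them, with a median log2 change of 1.00 against 0.21 for all genes and 0.73 after median-of-ratios scaling. Of unirradiated glands, the means of 76 were higher at ZT9 (median 0.38) and of 72 at ZT15 (0.34) than at ZT3, though the libraries overlapped: the median FPKM of the group was 409 and 459 at ZT3 and 643 and 442 at ZT9. It was 891 and 869 at 24 h. Against the mean of 3 control times the median change at 24 h was 0.80. Rps7 was 323 and 334 at ZT3 and 907 and 891 at 24 h.

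Genes of amino acid transport and synthesis were higher at ZT9 than at ZT3 in 17 of 18 cases (median log2 change 1.16), lower at 6 h than at ZT9 in 17 (-1.12) and lower at 24 h than at ZT3 in 15 (-0.69). Their median FPKM was 52.2 and 31.3 at ZT9, 13.4 and 16.4 at ZT3 and 26.3 and 30.0 at ZT15. Against the mean of 3 control times the median at 6 h was -0.56 and the median at 24 h was -1.24. Phgdh, which starts serine synthesis, was 36.1 and 42.7 at ZT3, 145 and 88.5 at ZT9, 73.4 and 54.4 at 6 h and 13.8 and 13.8 at 24 h. Sesn2, also a p53 target, was the exception at 6 h, at 10.1 and 3.64 at ZT9 and 24.8 and 18.9 at 6 h.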
